A study of Mus musculus with 9 samples.

How the data were processed

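The data were 9 RNA-seq libraries of mouse hippocampal tissue, 3 mice in each of 3 groups on a high-fat diet, as the labels give them. Per the labels' protocols, messenger RNA was captured on oligo(dT) beads, fragmented, copied with random hexamers, joined to adapters and amplified by PCR, with no strand marking described. The submitters' processing notes name StringTie 2.1.3b and the mouse build mm10. The aligner, the counting tool, the annotation release, the strand setting and the authors' test are not given in the sources used here.

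A single table for the whole series was used. Per the file headers it holds counts for each gene and library as the authors deposited them, and these were whole numbers without scaling between libraries. Per the file headers and the labels it also holds FPKM, which the authors computed as fragments scaled to gene length and library size. The authors further deposited a log2 fold change, a p-value, a q-value and a call for IPA against HFD and for Trp against HFD, with a dash where a gene was not tested. Every gene they called had q under 0.05 and more than a 2-fold change. All library columns were mapped to a sample through the names that the labels pair with each sample, and 0 columns were left over. The column codes WTB, HEB and HOB are not explained in the labels. The table lists 54513 gene symbols with coordinates. Of these 50671 (93%) occur in the GENCODE M21 reference, 1371 (2.7%) at the same position and 48582 (95.9%) on the same chromosome with the same length at another start. The coordinates are therefore printed as the table gives them, their build is not settled, and the reference was used only for gene types and overlap of exons.

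Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 18690, and libraries were scaled by TMM. A quasi-likelihood model with robust fitting and 1 mean per group, with no covariate and no block, was fitted to all 9 libraries. The contrasts were Trp against HFD, IPA against HFD and Trp against IPA. All tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. CPM are the deposited counts scaled to TMM-adjusted library sizes, errors of CPM are the SD of 3 libraries, and log2 CPM for lists and components used a prior count of 2. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1.

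Before the data were examined, the test, its alternatives, 42 gene lists with 1001 genes of brain cell types, neighbouring tissues, blood, signalling and metabolism, and the rule for naming genes were fixed. Of the list genes 928 were tested. The 41 lists with at least 5 tested members, all except the sex-linked genes, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list and with fry. Members were counted after adjustment over all genes and over the list alone. The genes named are, per comparison, the 10 higher and 10 lower with the largest absolute log2 fold change among those that passed, with a mean FPKM of at least 1 and group values that do not overlap, leaving out pseudogenes and symbols of predicted genes. If fewer than 5 qualified, the 5 with the smallest unadjusted p per direction are given. Up to 4 members with the smallest p per list described were added, and always, where measured, Ffar3, Ffar2, Ahr, Nr1i2, Cldn5, Ocln, Tjp1, Mfsd2a, Bdnf, Gfap, Aif1, Tnf, Il1b and Ttr. Genes near absent in 1 group, with groups that do not overlap and a mean CPM under 10% of that in the other group (a cut-off chosen after seeing the data), are counted in the closing section, and those that passed are named there.

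The alternatives were the DESeq2 1.42.0 Wald test, RLE and upper quartile scaling, no filter on low values, a mean FPKM of at least 5, limma-trend on log2 FPKM with pseudocounts of 0.5, 0.1 and 1 for genes with FPKM of at least 1 in at least 3 libraries, only the 6 libraries compared, the replicate number as a block, leaving out each of the 9 libraries, log2 fold thresholds of 1 and 0.58, and adjusted p under 0.01 and 0.1. Chosen after seeing the data were the striatal and choroid plexus list means as covariates, and a fit without HFD 3 and Trp 3. The correlation between both responses was set beside 20 draws of simulated groups without change against the real HFD libraries, with each gene drawn independently. In the same draws, the 64 genes with the smallest Trp p, and for the correlation also the 1 with the smallest IPA p, were set beside the genes called in the data, a step chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

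The procedure was tested on simulated data with counts drawn for the real genes and 200 genes changed. For Trp against HFD (18370 genes run) edgeR recovered 35.4% of 1.5-fold, 64.6% of 2-fold and 81.5% of 4-fold changes, with 7 false among 134 calls. For IPA against HFD (18410 genes run) it recovered 33.8%, 68.8% and 86.2% at the same folds, with 17 false among 147 calls. For Trp against IPA (18386 genes run) it recovered 38.5%, 60% and 89.1%, with 8 false among 140 calls. A microglia list raised 1.5-fold in each simulation was recovered by camera with the preset correlation, and 0 other lists were called. It was also recovered with an estimated correlation (adjusted p = 0.00102, 0.00076 and 0.00059, in the same order). Genes were drawn independently, so no list could move through tissue makeup, and the 0 other lists do not test such calls. When the 6 real libraries of a comparison were split in other ways, up to 19, 18 and 13 lists were called with the preset correlation, in the same order.

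Library totals ran from 40621084 to 50938746 counts, so that 3 counts, the most a count of 0 allows, equal 0.0584 to 0.075 CPM at the TMM-adjusted sizes. PCR copies carry no molecular identifiers, and floors of this kind cover counting error only. Replicates varied more than counting error, with a chi-square per degree of freedom of 13.5 to 71.1 between the 9 pairs of libraries within groups for genes of at least 20 counts. The 10 most abundant genes held 7.7% to 11.4% of the counts. No library was left out of the main analysis. Age, strain, litter, collection day and sequencing batch are not given in the sources used here, so that no batch could be compared with the groups.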

Results

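Polyadenylated RNA of tissue labelled as mouse hippocampus was sequenced in 9 libraries. They came from 3 groups of 3 mice, all kept on a high-fat diet for 12 weeks. The HFD group had this diet alone. The Trp group ate the same diet with the amino acid tryptophan added at 0.5% by weight. The IPA group received indole-3-propionic acid (IPA), a product of tryptophan made by gut bacteria that lacks tryptophan's alpha-amino group, by daily gavage at 100 mg per kg body weight. No group on ordinary chow was among the libraries. The columns of HFD, IPA and Trp in the authors' table carry the codes WTB, HEB and HOB, which the labels pair with the samples and do not explain. The groups are named here by their labels. Neither the labels nor the table settle whether these columns hold the mice of this diet study or those of another series, such as one of genotypes. If they hold another series, the comparisons below are not of diets. The labels also do not give whether the groups differ in anything besides the treatment. Total counts were 46327289, 50385774 and 43111819 in HFD 1 to 3, 41509630, 40621084 and 42565593 in IPA 1 to 3, and 50938746, 40660032 and 47718379 in Trp 1 to 3. Between 23940 and 24947 genes were detected per library, and 18690 were tested. A count of 0 allowed up to 0.0584 to 0.075 CPM, the counts scaled to TMM-adjusted library size, by library. Correlations of log2 CPM across genes ran from 0.9783 to 0.988 within groups and from 0.9741 to 0.9878 between groups, and genes are not independent replicates. Xist gave 4365 to 7267 counts, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty gave 0 counts in every library, the pattern of female mice.

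Transcripts of neighbouring brain regions varied between libraries of the same group. Drd1, the D1 dopamine receptor of striatal neurons, stood at 44.4, 88.6 and 20.5 CPM in HFD 1 to 3, at 82.0, 70.9 and 102 CPM in IPA 1 to 3, and at 49.8, 73.1 and 59.1 CPM in Trp 1 to 3. The mean log2 CPM of 22 striatal markers was 5.67 ± 0.80 (SD, n = 3) in HFD, 6.51 ± 0.20 in IPA and 6.12 ± 0.25 in Trp. The hippocampal lists had lower means in HFD, IPA and Trp. These were 4.30, 4.03 and 4.06 for dentate granule cells and 4.41, 4.15 and 4.24 for pyramidal cells of the CA fields. Means of lists with different genes do not measure shares of tissue, so how much hippocampus the libraries hold is not settled. HFD 3 had the lowest striatal value, 4.84. HFD 3 also had the highest mean of the thalamus and habenula list, 4.41, and of the blood cell list, 5.12. Slc6a3, the dopamine transporter, reached 11.1 CPM in HFD 3 and 0.168 to 0.751 CPM in the other 8 libraries. HFD 3 lay at -58.3 on the first principal component, which held 22.2% of the variance. The second component (19.1%) did not sort the libraries by group. On it HFD 1, HFD 2 and Trp 3 lay at 34.5, 28.5 and 25.7. HFD 3 lay at -14.4 there, the IPA libraries at -5.30 to -16.7, and Trp 1 and Trp 2 at -31.3 and -10.9. The mean of 27 choroid plexus markers ran from -0.31 to 3.50 within the Trp group. Its most abundant member Ttr, the thyroxine carrier transthyretin, was measured at 1288 CPM in Trp 1 and 25.7 CPM in Trp 3. Pmch, the hypothalamic melanin-concentrating hormone gene, ran from 0.52 CPM in IPA 3 to 131 CPM in Trp 3.

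The comparison of the Trp with the HFD group asks how transcripts of tissue labelled as hippocampus differ where the labels give added tryptophan. The study is concerned with cognition, the blood-brain barrier and the fatty acid receptor FFAR3. Ctss, the lysosomal protease cathepsin S and a microglial gene, rose 2.14-fold in the Trp group (log2 fold change 1.10, SE 0.12, n = 3 per group). It was 1 of 5 among 25 microglia markers that passed, and the call on that list was lost with an estimated correlation (adjusted p = 0.359). Mfsd2a, the lysolipid transporter of the blood-brain barrier endothelium, rose 2.07-fold (1.05, SE 0.13), and Edn1, the vasoconstrictor peptide endothelin-1, rose 3.55-fold (1.83, SE 0.23). Fos, which neurons induce with activity, fell by 1.56 (SE 0.22) and Sox4, of newborn neurons, by 0.72 (SE 0.12) on the log2 scale. They were among 2 of 30 immediate early and 4 of 25 neurogenesis genes that passed, and both list calls were lost with an estimated correlation (adjusted p = 0.373 and 0.0881). Antigen presentation genes H2-Q4 and H2-K1 fell by 1.51 (SE 0.21) and 0.83 (SE 0.14). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 64 genes passed at adjusted p under 0.05, 40 higher and 24 lower. The list calls rest on a preset correlation between genes, and with an estimated correlation the smallest adjusted p of a list was 0.0881.

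Of 25 microglia markers, 24 were higher in Trp than in HFD, with a median log2 fold change of 0.61. The list rose (camera adjusted p = 4.96e-22, adjusted p = 0.359 with an estimated correlation), and its mean log2 CPM was 3.60 ± 0.09 in HFD, 3.69 ± 0.03 in IPA and 4.22 ± 0.21 in Trp (SD, n = 3). 5 members passed over all genes and 21 passed when adjusted over the list alone. Ctss stood at 23.6 ± 2.97 CPM in HFD and 50.6 ± 6.11 CPM in Trp. Selplg, the selectin ligand PSGL-1, rose by 0.92 on the log2 scale (SE 0.12, adjusted p = 0.00803). C1qb, a chain of complement C1q, rose by 0.78 (SE 0.11, adjusted p = 0.0139). Aif1, the microglial marker IBA1, had a log2 fold change of 0.52 (adjusted p = 0.275) and did not pass. The list of activated microglia genes did not move as a group (adjusted p = 0.662), nor did the list of cytokine and inflammasome genes (adjusted p = 0.568). Il1b, the cytokine interleukin-1 beta, had a log2 fold change of 0.41 (adjusted p = 0.762), and Tnf, with 0 to 3 counts per library, was not tested.

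Of 22 glucocorticoid-induced genes, 19 were higher in Trp (median 0.59). The list rose (adjusted p = 6.82e-10, adjusted p = 0.424 with an estimated correlation). 3 members passed over all genes, and 13 higher and 1 lower passed when adjusted over the list alone. Hif3a, an inhibitory hypoxia-inducible factor subunit, rose by 1.77 on the log2 scale (SE 0.25, adjusted p = 0.012). Sult1a1, a phenol sulfotransferase whose exons overlap those of Sgf29 in the annotation, rose by 1.61 (SE 0.24, adjusted p = 0.0225), and Mt1, a metallothionein, by 0.52 (SE 0.10, adjusted p = 0.0415). Plin4, a lipid droplet coat protein, was measured at 1.42 ± 1.06 CPM in HFD, 21.3 ± 6.29 in IPA and 42.8 ± 21.5 in Trp, and its log2 fold change of 4.94 (SE 0.70, adjusted p = 0.0638) did not pass.

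Immediate early genes, which neurons induce with activity, fell as a list, with 28 of 30 members lower (median -0.43, adjusted p = 4.84e-10, adjusted p = 0.373 with an estimated correlation). 2 members passed over all genes and 11 when adjusted over the list alone. Fos, a subunit of the transcription factor AP-1, stood at 28.4 ± 8.18 CPM in HFD, 10.6 ± 2.24 in IPA and 9.64 ± 0.96 in Trp (adjusted p = 0.0207 for Trp). Egr1, a zinc finger transcription factor, fell by 0.84 (SE 0.15, adjusted p = 0.0415). Egr4 (-1.05, adjusted p = 0.196) and Nr4a3 (-1.29, adjusted p = 0.2) did not pass. Bdnf, the brain-derived neurotrophic factor, had a log2 fold change of -0.31 (adjusted p = 0.481).

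Adult neurogenesis genes fell as a list, with 22 of 25 members lower (median -0.44, adjusted p = 1.51e-07, adjusted p = 0.0881 with an estimated correlation). 4 passed over all genes and 8 when adjusted over the list alone. Nes, the intermediate filament nestin of neural progenitors, fell by 0.81 (SE 0.13, adjusted p = 0.0225). The transcription factors Sox4 and Sox11 fell by 0.72 (adjusted p = 0.0246) and 0.55 (adjusted p = 0.0378). Dpysl3, a growth cone protein, fell by 0.57 (adjusted p = 0.0271). Marcksl1, a regulator of actin at the membrane that is on the dentate granule cell list, fell by 0.94 (SE 0.14, adjusted p = 0.0207). The 20 genes of that list fell slightly (median -0.09, adjusted p = 0.0425, adjusted p = 0.506 with an estimated correlation), with 1 passing over all genes and 2 when adjusted over the list alone. Its members Npnt (-0.37, adjusted p = 0.213) and Stxbp6 (-0.32, adjusted p = 0.337) did not pass. The call on the dentate list ended when HFD 1, any 1 of the IPA libraries, Trp 2 or Trp 3 was left out, with adjusted p of 0.152, 0.0546, 0.0531, 0.0522, 0.116 and 0.247 in that order.

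Interferon-stimulated genes fell as a list, with 22 of 28 members lower (median -0.30, adjusted p = 2.28e-05, adjusted p = 0.373 with an estimated correlation). Gbp3, an interferon-induced guanylate-binding protein, fell by 1.02 (SE 0.16, adjusted p = 0.0206). It was the 1 member that passed over all genes, and 3 passed when adjusted over the list alone. Gbp2 (-1.05, adjusted p = 0.0752), Iigp1 (-1.43, adjusted p = 0.15) and Ifi44 (-1.25, adjusted p = 0.264) did not pass. H2-Q4 stood at 5.68 ± 0.592 CPM in HFD and 1.99 ± 0.244 CPM in Trp, and reads of this MHC class I family can be shared between its copies.

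At the blood-brain barrier, Mfsd2a was measured at 15.5 ± 1.97 CPM in HFD, 23.9 ± 1.46 in IPA and 32.1 ± 5.35 in Trp (SD, n = 3), with adjusted p = 0.00568 for Trp against HFD. It was the 1 gene of 22 barrier transport genes that passed over all genes. Over the list alone 3 were higher and 4 lower, and the list did not move (adjusted p = 0.69). The list of 20 tight and adherens junction genes did not move either (adjusted p = 0.458). Its median was -0.04 and the test pointed down, while its mean was 0.00, and 1 gene fell when adjusted over the list alone. Log2 fold changes were -0.34 for Cldn5 (95% interval -0.76 to 0.09, adjusted p = 0.559), -0.32 for Ocln (-0.72 to 0.09, adjusted p = 0.573) and -0.10 for Tjp1 (-0.35 to 0.14, adjusted p = 0.801), which encode claudin-5, occludin and ZO-1. Endothelial markers fell slightly as a list, with 17 of 26 lower (median -0.22, adjusted p = 0.00499, adjusted p = 0.506 with an estimated correlation). Its leading members were Itm2a (-0.44, adjusted p = 0.213), Podxl (-0.30, adjusted p = 0.263) and Flt1 (-0.31, adjusted p = 0.268). Mural cell markers were lower in 15 of 17 (median -0.15, adjusted p = 0.0422, adjusted p = 0.702 with an estimated correlation), with Mcam at -0.61 (adjusted p = 0.315) and Acta2 at -0.48 (adjusted p = 0.429). The endothelial call ended without HFD 3 (adjusted p = 0.0749), and the mural call ended without HFD 3, Trp 1 or Trp 2 (adjusted p = 0.448, 0.222 and 0.194).

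Ffar3, the short-chain fatty acid receptor of the study's question, gave 0 to 19 counts per library. Its log2 fold change was -1.91 (SE 1.07, 95% interval -4.26 to 0.44, adjusted p = 0.551), so a difference was not detectable at this depth. Ffar2 gave 0 to 4 counts, and Nr1i2, the pregnane X receptor, gave 0 counts in every library, and neither was tested. Ahr, the aryl hydrocarbon receptor, had a log2 fold change of -0.20 (adjusted p = 0.626). None of the lists of fatty acid and indole receptors (adjusted p = 0.239), of tryptophan-metabolising enzymes (0.231), of aryl hydrocarbon and pregnane X receptor targets (0.237) or of serotonin receptors (0.775) passed. The astrocyte marker Gfap had a log2 fold change of -0.47 (adjusted p = 0.6).

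Markers of neighbouring tissue and blood moved in the same comparison. All 22 striatal markers were higher in Trp (median 0.26, adjusted p = 0.00125, adjusted p = 0.702 with an estimated correlation), as Pde10a at 0.58 (adjusted p = 0.719) and Tac1 at 0.44 (adjusted p = 0.719), and this call ended without HFD 3 (adjusted p = 0.812). Of 20 ependymal and cilia genes 19 were higher (median 0.41, adjusted p = 9.69e-04, adjusted p = 0.702 with an estimated correlation), and the call ended without Trp 1 (adjusted p = 0.167). The member Tekt4, a tektin of cilia and sperm tails, rose 4.72-fold (2.24, SE 0.27, adjusted p = 0.00568), from 0.816 ± 0.308 CPM in HFD to 3.84 ± 0.381 CPM in Trp, and was the 1 member to pass over all genes and over the list alone. Foxj1, the ciliogenesis regulator, stood at 0.53 (adjusted p = 0.467). Blood cell genes were lower in 9 of 11 (median -0.82, adjusted p = 0.00131, adjusted p = 0.424 with an estimated correlation), none over all genes and 5 when adjusted over the list alone, as Alas2 of red cell haem synthesis at -2.37 (adjusted p = 0.117) and Hba-a1, an alpha-globin, at -1.72 (adjusted p = 0.282). Hypothalamic genes were higher in 15 of 19 (median 0.30, adjusted p = 0.0373, adjusted p = 0.702 with an estimated correlation), as Peg10 at 0.61 (adjusted p = 0.13) and Sst at 0.49 (adjusted p = 0.283), with Pomc at -0.80 (adjusted p = 0.365). That call ended without HFD 2, HFD 3, Trp 2 or Trp 3 (adjusted p = 0.104, 0.0729, 0.0801 and 0.15).

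With striatal and choroid plexus means as covariates, 3 of the 16 list calls of Trp against HFD ended, those of mural (adjusted p = 0.6), ribosomal protein (0.499) and striatal genes (0.748), the last being a covariate itself. Without both HFD 3 and Trp 3, the calls of the dentate (adjusted p = 0.135), hypothalamic (0.272), ribosomal protein (0.0526) and striatal lists (0.81) ended, and with a replicate block that of the dentate list (0.0631).

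Small coordinated shifts without a gene that passed were measured in 4 further lists. Synaptic genes were lower in 34 of 40 (median -0.13, adjusted p = 2.64e-04, adjusted p = 0.506 with an estimated correlation), as Syn2 at -0.32 (adjusted p = 0.221) and Nrxn3 at -0.29 (adjusted p = 0.23). Heat shock and unfolded protein response genes were higher in 23 of 27 (median 0.22, adjusted p = 2.91e-04, adjusted p = 0.569 with an estimated correlation), as the chaperones Hsp90b1 at 0.40 (adjusted p = 0.217) and Hspa5 at 0.47 (adjusted p = 0.31). Cholesterol synthesis genes were lower in 20 of 24 (median -0.15, adjusted p = 0.00158, adjusted p = 0.487 with an estimated correlation), as Mvd at -0.44 (adjusted p = 0.233). Ribosomal protein genes were lower in 68 of 76 (median -0.08, adjusted p = 5.56e-04, adjusted p = 0.786 with an estimated correlation), and this call ended without HFD 3 (adjusted p = 0.313). Beyond those named above, the other lists of cell types, tissues and pathways had adjusted p from 0.0945 for oligodendrocyte genes to 0.915 for the nuclear respiratory chain. The signs of the median, the mean and the test differed within 6 lists, none of which passed: junction, serotonin receptor, reactive astrocyte, neurotrophin, clock and amyloid genes. Ttr, of the choroid plexus list (adjusted p = 0.662), had a log2 fold change of 0.98 (95% interval -2.24 to 4.20).

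Further genes among the 10 with the largest rise were Tmprss6, a membrane serine protease (1.48, SE 0.25), Kirrel2 (1.26, SE 0.21), the lens crystallin gene Crybb1 (1.24, SE 0.23), Smim3 (1.17, SE 0.15) and Aass, of lysine breakdown (1.09, SE 0.20). Among the 10 with the largest fall were also Nrep (-0.83, SE 0.12) and the secreted ligand gene Wnt9a (-0.75, SE 0.14). Gper1, the G protein-coupled oestrogen receptor, was too low in FPKM for the naming rule and was chosen after its values were seen. It fell by 4.98 on the log2 scale (SE 0.52, adjusted p = 0.0049), from 81 to 94 counts in HFD to 0 to 4 counts in Trp, and the labels do not give whether the mice of the groups share 1 genotype. In the authors' table, whose coordinates match GENCODE M21 for 2.7% of the shared symbols so that their build is not settled, Ctss lies on chromosome 3 from 95434097 to 95463714, Mfsd2a on 4 from 122840643 to 122854981, Fos on 12 from 85520664 to 85524047 and Gper1 on 5 from 139408906 to 139413555. Exons of Edn1 overlap those of Gm47118 and exons of H2-Q4 those of Gm11131.

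**Figure D1:**
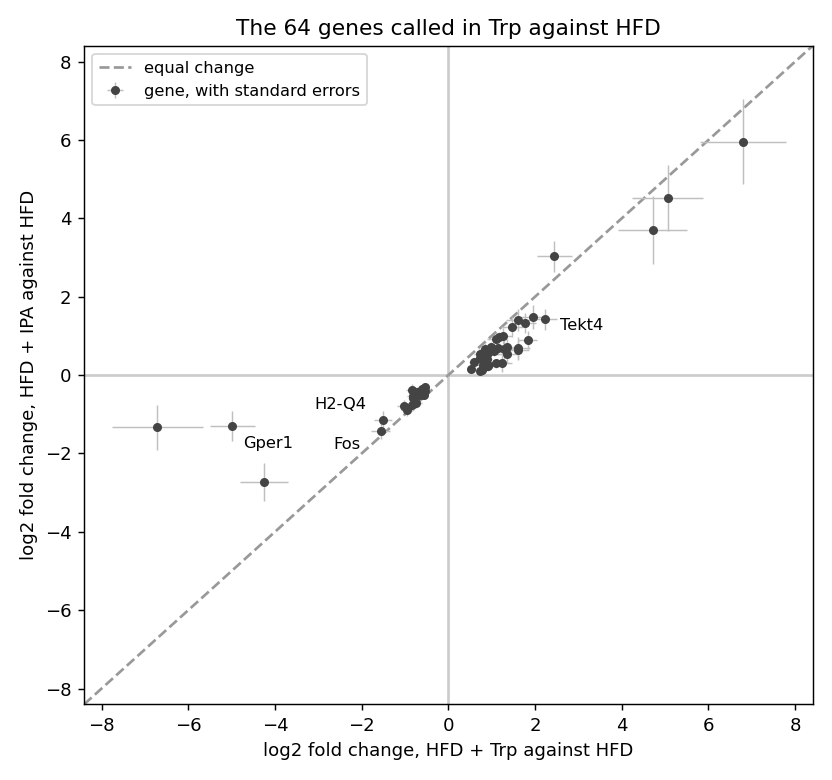
Log2 fold change against HFD in the Trp group (horizontal) and in the IPA group (vertical) of the 64 genes that passed in Trp against HFD, with standard errors, 3 libraries per group and a dashed line of equal change. All 64 lie on the same side of 0 in both, and 63 have the smaller change in IPA, where genes picked by their Trp change in simulated groups without change gave 55 to 63 and 58 to 64.

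All 64 genes had groups that did not overlap, against 2894 of all tested genes (15.5%, where chance gives 10%), and 2112 genes (11.3%) had an unadjusted p under 0.05. Evenly spread p would give 934, while the 9 other splits of these 6 libraries gave 242 to 2966. The highest came from setting HFD 1, HFD 2 and Trp 3 against HFD 3, Trp 1 and Trp 2. The count that passed was 33, 26 and 323 without HFD 1, 2 and 3, 39, 25 and 33 without IPA 1, 2 and 3, and 22, 13 and 81 without Trp 1, 2 and 3, and all 64 were among the 323. Of the genes named above that passed, Tekt4, Edn1, Ctss, Mfsd2a, Selplg and Gper1 stayed under 0.05 without any single library. The others lost the call without at least 1 library, H2-Q4 without Trp 1 (adjusted p = 0.05), Nrep and Smim3 without Trp 2 (adjusted p = 0.0744 and 0.051), C1qb without HFD 2 or Trp 2 (adjusted p up to 0.0755), and at the other end Egr1 and Mt1 without any 1 of 8 libraries (up to 0.2 and 0.25). DESeq2 called 309 genes, 60 of the 64 among them, and limma on log2 FPKM called 60, of which 36 were among the 64 and 90% were higher against 62.5% here. The authors' own table tested 15337 genes and called 65 (48 up, 17 down), each with q under 0.05 and more than a 2-fold change, and 22 of the 64 were among them. Of the 64, 58 were tested by the authors, all 58 with their q under 0.05, and 28 of the 64 reached a 2-fold change here.

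The comparison of the IPA with the HFD group asks how transcripts differ where the labels give the bacterial metabolite by gavage on the same diet. In it 1 gene passed, Gm10774, a processed pseudogene whose exons overlap Usp50 and which is outside the naming rule and was chosen after its value was seen (log2 fold change -4.56, adjusted p = 0.0212 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per group). No named gene passed. Inhba, the activin A subunit, had a log2 fold change of 0.93 (SE 0.14) and Mme, the amyloid-degrading protease neprilysin, of 1.11 (SE 0.19). Fos had a log2 fold change of -1.42 (SE 0.22). As groups, striatal markers and glucocorticoid-induced genes rose, and endothelial, mural, interferon-stimulated and neurogenesis genes fell, under the list test with its preset correlation alone. With an estimated correlation none of the lists kept its call, and their smallest adjusted p was 0.2.

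Among the 5 smallest unadjusted p per direction under the naming rule, the higher genes were Inhba (adjusted p = 0.106), Smim3 (0.96, SE 0.15, adjusted p = 0.126), Kctd8 (0.72, SE 0.12, adjusted p = 0.134), Mme (13.3 ± 3.77 CPM in HFD and 28.9 ± 4.68 in IPA, adjusted p = 0.14) and Dio2, the deiodinase that activates thyroid hormone (0.55, SE 0.10, adjusted p = 0.14). The lower were Marcksl1 (-0.90, SE 0.14, adjusted p = 0.134), Ctnnbip1, an inhibitor of beta-catenin (-0.57, SE 0.09, adjusted p = 0.134), Fos (adjusted p = 0.134), Mpzl1 (-0.70, SE 0.12, adjusted p = 0.14) and Nkx2-2, a transcription factor of the oligodendrocyte lineage (-1.03, SE 0.18, adjusted p = 0.14). None of these 10 passed in edgeR. The rule's FPKM limit left out Usp50 (3.03, SE 0.41, adjusted p = 0.0537), whose exons overlap Gm10774, and Gm49395 (-2.72, adjusted p = 0.14). Usp50 was thus higher in IPA where Gm10774 was lower, and whether reads moved between these overlapping genes was not tested.

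Endothelial markers fell as a list, with 24 of 26 lower (median -0.30, adjusted p = 2.50e-08, adjusted p = 0.2 with an estimated correlation). No member passed over all genes and 11 fell when adjusted over the list alone. The values were -0.74 for Kdr, the VEGF receptor (adjusted p = 0.259), -0.71 for Vwf (adjusted p = 0.32), -0.48 for Slco1a4 (adjusted p = 0.296) and -0.60 for Cldn5 (95% interval -1.03 to -0.18, adjusted p = 0.349). Mural cell markers fell with 16 of 17 lower (median -0.41, adjusted p = 4.33e-07, adjusted p = 0.39 with an estimated correlation) and 5 past the threshold when adjusted over the list alone, as Myh11 at -0.63 (adjusted p = 0.257) and Acta2 at -0.73 (adjusted p = 0.328), both of smooth muscle. Meningeal and vascular fibroblast genes were lower in 16 of 20 (median -0.72, adjusted p = 4.92e-04, adjusted p = 0.653 with an estimated correlation), as the collagens Col3a1 at -1.76 (adjusted p = 0.211) and Col1a1 at -1.60 (adjusted p = 0.25), with 3 past the threshold over the list alone, and this call ended without HFD 3 (adjusted p = 0.155). Neither barrier list passed, at adjusted p = 0.0805 for transport, with 1 higher and 5 lower when adjusted over the list alone, and 0.295 for junctions, with 1 lower. Ocln and Tjp1 had log2 fold changes of -0.03 (adjusted p = 0.972) and 0.10 (adjusted p = 0.795), and Mfsd2a of 0.63 (SE 0.13, adjusted p = 0.167).

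Interferon-stimulated genes fell with 25 of 28 lower (median -0.42, adjusted p = 2.68e-07, adjusted p = 0.2 with an estimated correlation), 2 of them past the threshold over the list alone, as Gbp3 at -0.78 (adjusted p = 0.148) and Oasl2 at -0.88 (adjusted p = 0.257). Neurogenesis genes fell with 21 of 25 lower (median -0.33, adjusted p = 1.27e-05, adjusted p = 0.2 with an estimated correlation) and 4 past the threshold over the list alone, as Dpysl3 at -0.51 (adjusted p = 0.142) and Nes at -0.54 (adjusted p = 0.231). Immediate early genes fell with 25 of 30 lower (median -0.36, adjusted p = 1.27e-05, adjusted p = 0.507 with an estimated correlation) and 2 past the threshold over the list alone, as Jun at -0.43 (adjusted p = 0.191) and Ier2 at -1.16 (adjusted p = 0.332). Glucocorticoid-induced genes rose with 19 of 22 higher (median 0.42, adjusted p = 3.09e-07, adjusted p = 0.507 with an estimated correlation), and 9 higher and 2 lower passed over the list alone. Hif3a stood at 1.34 (SE 0.25, adjusted p = 0.142), Plin4 at 3.93 (SE 0.68, adjusted p = 0.204) and Xdh, xanthine dehydrogenase, at 1.58 (SE 0.37, adjusted p = 0.28). The microglia list did not pass (median 0.10, 16 of 25 higher, adjusted p = 0.119), and Aif1 had a log2 fold change of 0.05 (adjusted p = 0.945).

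Neighbouring tissue moved with the IPA group as well. All 22 striatal markers were higher (median 0.72, adjusted p = 2.98e-10, adjusted p = 0.507 with an estimated correlation), as Foxp1 at 0.42 (adjusted p = 0.449) and Isl1 at 0.48 (adjusted p = 0.363). All 27 choroid plexus genes were higher (median 0.95, adjusted p = 5.97e-04, adjusted p = 0.676 with an estimated correlation), as Kcnj13 at 1.49 (adjusted p = 0.677), a call that ended without HFD 2 or IPA 2 (adjusted p = 0.0628 and 0.0529). All 20 ependymal genes were higher (median 0.62, adjusted p = 4.79e-07, adjusted p = 0.507 with an estimated correlation), as Tekt4 at 1.42 (adjusted p = 0.144), the 1 that passed over the list alone. Blood cell genes were lower in 10 of 11 (median -1.74, adjusted p = 4.56e-05, adjusted p = 0.274 with an estimated correlation), as Hba-a1 at -1.92 (adjusted p = 0.332), and 6 passed over the list alone. Thalamus and habenula genes were lower in 19 of 22 (median -0.52, adjusted p = 0.03, adjusted p = 0.676 with an estimated correlation), as Lef1 at -1.17 (adjusted p = 0.403), and this call ended without HFD 3 or IPA 3 (adjusted p = 0.817 and 0.433).

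Ribosomal protein genes were lower in 74 of 76 (median -0.12, adjusted p = 1.11e-05, adjusted p = 0.676 with an estimated correlation), and the call ended without HFD 3 (adjusted p = 0.0838) and turned upward with striatal and choroid plexus means as covariates (adjusted p = 1.5e-05). Heat shock and unfolded protein response genes were higher in 23 of 27 (median 0.16, adjusted p = 2.75e-04, adjusted p = 0.647 with an estimated correlation), as Hspa5 at 0.51 (adjusted p = 0.349). Mitochondrially encoded genes were higher in 11 of 13 (median 0.14, adjusted p = 0.0461, adjusted p = 0.676 with an estimated correlation), with mt-Nd5 at 0.43 (adjusted p = 0.322) and 2 past the threshold over the list alone. That call ended without HFD 1, HFD 2, IPA 1 or Trp 2 (adjusted p = 0.434, 0.141, 0.542 and 0.0603). Reactive astrocyte genes were lower in 15 of 24 (median -0.16, adjusted p = 0.0493, adjusted p = 0.676 with an estimated correlation), as Cd44 at -0.58 (adjusted p = 0.393), and the call ended without HFD 3, IPA 1, Trp 1 or Trp 2 (adjusted p = 0.893, 0.282, 0.102 and 0.0735). The other lists that did not pass had adjusted p from 0.065 for oligodendrocyte precursors to 0.808 for astrocyte markers. With the covariates, 8 of the 16 list calls of IPA against HFD ended in their direction. These were the mural (adjusted p = 0.236), meningeal (0.111), reactive astrocyte (0.663), ependymal (0.639), thalamic (0.06) and ribosomal protein lists, and the striatal (0.743) and choroid plexus (0.702) lists that are covariates themselves. Without HFD 3 and Trp 3 the meningeal (adjusted p = 0.28), reactive astrocyte (0.876), thalamic (0.711) and ribosomal protein calls (0.0891) ended. A replicate block ended the reactive astrocyte (0.0607), thalamic (0.0505) and mitochondrial calls (0.0655), and upper quartile scaling the reactive astrocyte (0.0668) and thalamic calls (0.0592). Ffar3 had a log2 fold change of -0.67 (95% interval -2.79 to 1.45, adjusted p = 0.844), Ahr of -0.17 (0.69), Bdnf of -0.22 (0.644), Gfap of -0.66 (0.477), Il1b of -1.13 (0.442) and Ttr of 1.14 (0.805).

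At an unadjusted p under 0.05, edgeR gave 1946 genes (10.4%), where evenly spread p would give 934 and the 9 other splits of the 6 libraries gave 247 to 2040, and 2841 genes (15.2%, where chance gives 10%) had groups that did not overlap. DESeq2 called 168 genes. The edgeR count was 7 without HFD 2, 52 without HFD 3, 0 without IPA 1, IPA 2 or Trp 1, and 3 without Trp 2 or Trp 3. Gm10774 kept its call in 4 of 9 such fits, those without HFD 2, HFD 3, Trp 2 or Trp 3. It lost the call in 5, and without HFD 1 or IPA 3 the 1 gene that passed was another. It was not among the 168 calls of DESeq2, nor the 1 gene that passed with the covariates. The authors' table called 46 of 15236 genes (25 up, 21 down), and the IPA call made here was not among the genes they tested.

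**Figure D2:**
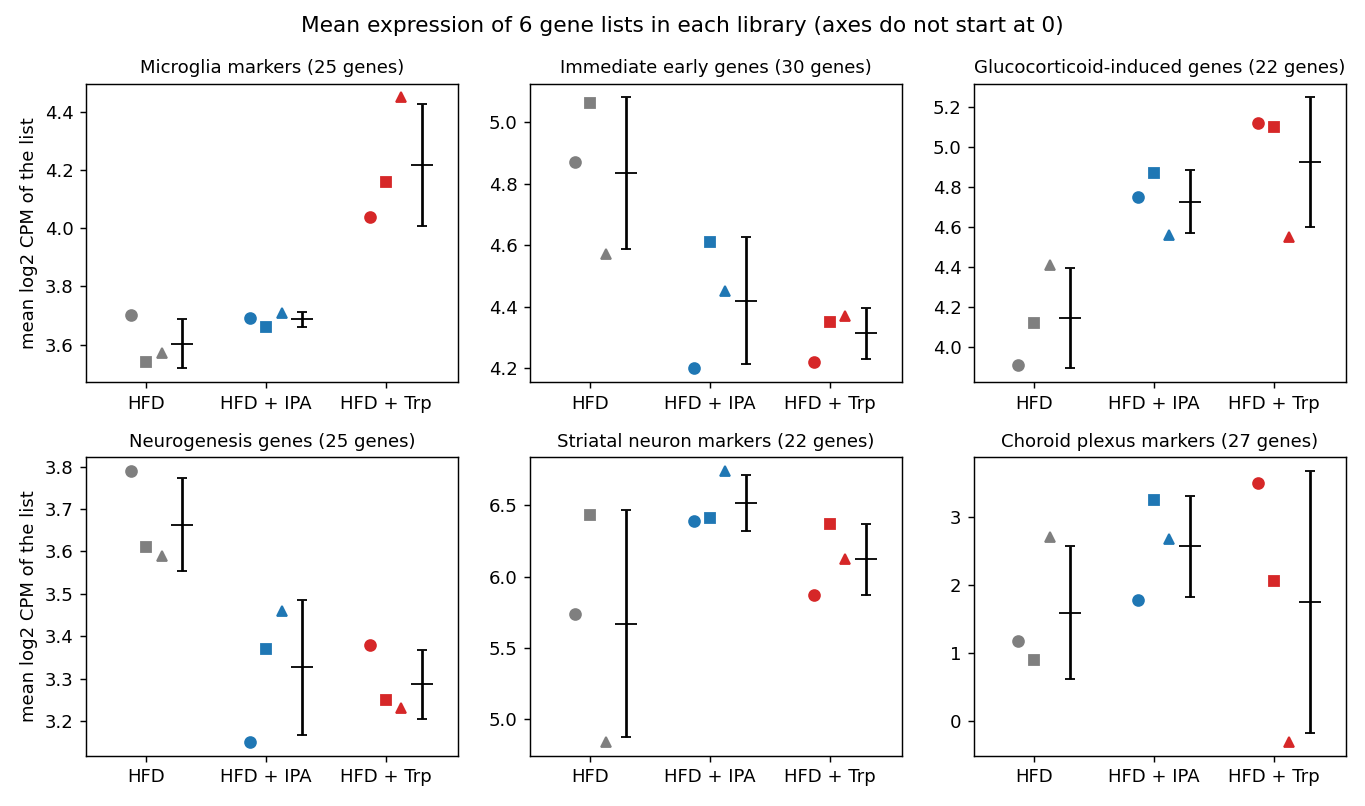
Mean log2 CPM per library of 6 gene lists in the HFD, IPA and Trp groups, with replicate 1 as circles, 2 as squares and 3 as triangles, bars for the mean ± SD (n = 3) and axes that do not start at 0. The microglia means of the Trp libraries, 4.04 to 4.45, lie above all others, and HFD 3 has the lowest striatal mean, 4.84.

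The direct comparison of Trp with IPA asks whether the groups labelled with the related molecules differed, given at different doses and by different routes. No gene passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where 840 genes (4.5%) had an unadjusted p under 0.05, DESeq2 called 15 and limma called 2. The smallest adjusted p, 0.102, was shared by 3 genes. Outside the naming rule and chosen after their values were seen, Gper1 had a log2 fold change of -3.68 (SE 0.54, Trp at 7.79% of IPA, 95% interval 3.47 to 17.5) and the pseudogene Gm10774 of 3.97 (SE 0.54). The third was Ctss at 29.1 ± 2.38 CPM in IPA and 50.6 ± 6.11 CPM in Trp, a log2 fold change of 0.80 (SE 0.12, n = 3 per group, 95% interval 0.54 to 1.05). As a group, microglia genes rose in Trp over IPA, with 25 of 25 higher and a median of 0.53 under the list test with its preset correlation alone, a call lost with an estimated correlation (adjusted p = 0.425).

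The microglia list had adjusted p = 3.24e-28, and adjusted p = 0.425 with an estimated correlation. No member passed over all genes, while 23 passed when adjusted over the list alone. Among the 5 smallest unadjusted p under the naming rule, with its mean FPKM of at least 1 and without pseudogenes, the higher genes besides Ctss were Fcgr3, a low-affinity receptor for IgG (0.65, SE 0.10, adjusted p = 0.126), Selplg (0.69, SE 0.12, adjusted p = 0.252), C1qb (0.64, SE 0.11, adjusted p = 0.252) and the zinc finger gene Zfp973 (1.30, SE 0.24, adjusted p = 0.252). The lower genes were Osbpl8 (-0.50, SE 0.12), Spock3 (-0.50), Homer1, a postsynaptic scaffold (-0.55, SE 0.14), Lrrtm4 (-0.33) and Acvr1c (-0.55), all with adjusted p = 0.987. The FPKM limit left out Gper1 above and Apol7a (-5.39, SE 1.20, adjusted p = 0.96), which had smaller p than these 5.

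Differences in the barrier and receptor genes between both groups were bounded as follows. The log2 fold change of Trp over IPA was 0.42 for Mfsd2a (95% interval 0.14 to 0.70), 0.27 for Cldn5 (-0.16 to 0.69), 0.47 for Aif1 (0.10 to 0.85), -0.29 for Ocln (-0.70 to 0.12), -0.20 for Tjp1 (-0.45 to 0.05) and -1.24 for Ffar3 (-3.74 to 1.26), each with adjusted p = 0.987. Il1b stood at 1.54 (0.58 to 2.51, adjusted p = 0.987), Bdnf at -0.09, Gfap at 0.20, Ahr at -0.03 (adjusted p = 0.991) and Ttr at -0.16 (adjusted p = 0.997). The list of fatty acid and indole receptors rose with 4 of 7 higher (median 0.31, adjusted p = 0.0168, adjusted p = 0.486 with an estimated correlation), as Gpr35 at 0.96 and Gpr84 at 0.79. Tryptophan-metabolising enzymes rose with 13 of 18 higher (median 0.17, adjusted p = 0.0223, adjusted p = 0.486 with an estimated correlation), as Tph2 at 0.93 and Tph1 at 0.91, the hydroxylases that start serotonin synthesis. Barrier transport genes rose with 16 of 22 higher (median 0.08, adjusted p = 0.0437, adjusted p = 0.486 with an estimated correlation). The receptor call ended without IPA 2 or Trp 2 (adjusted p = 0.0992 and 0.054), and the enzyme call without IPA 2, IPA 3, Trp 1 or Trp 2 (adjusted p = 0.15, 0.114, 0.113 and 0.159). The transport call ended without HFD 2, HFD 3, IPA 1, IPA 3, Trp 1, Trp 2 or Trp 3 (adjusted p = 0.068, 0.0665, 0.315, 0.0606, 0.0873, 0.0566 and 0.0646). The junction list did not pass (adjusted p = 0.794).

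Vascular lists were higher in Trp than in IPA, with 21 of 26 endothelial markers (median 0.14, adjusted p = 0.00103, adjusted p = 0.486 with an estimated correlation), as Eng at 0.43, and 16 of 17 mural markers (median 0.26, adjusted p = 5.42e-04, adjusted p = 0.486 with an estimated correlation), as Pdgfrb at 0.45. Meningeal genes were higher in 18 of 20 (median 0.48, adjusted p = 0.00253, adjusted p = 0.675 with an estimated correlation), until Trp 1 or Trp 2 was left out (adjusted p = 0.0661 and 0.0693). Glucocorticoid-induced genes were higher in 16 of 22 (median 0.23, adjusted p = 0.0223, adjusted p = 0.785 with an estimated correlation), as Sult1a1 at 0.98 and Mt2 at 0.45, with 3 past the threshold over the list alone, until IPA 3, Trp 1 or Trp 2 was left out (adjusted p = 0.27, 0.49 and 0.262). Astrocyte markers were higher in 14 of 22 (median 0.07, adjusted p = 0.0437, adjusted p = 0.785 with an estimated correlation), until HFD 1, IPA 2, IPA 3, Trp 1 or Trp 2 was left out (adjusted p = 0.0552, 0.172, 0.398, 0.147 and 0.278). Hypothalamic genes were higher in 17 of 19 (median 0.30, adjusted p = 0.00185, adjusted p = 0.486 with an estimated correlation), as Pomc at 0.77, until IPA 3 was left out (adjusted p = 0.299).

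Lower in Trp than in IPA were all 13 mitochondrially encoded genes (median -0.29, adjusted p = 3.42e-06, adjusted p = 0.539 with an estimated correlation), as mt-Nd4 at -0.36, and all 22 striatal markers (median -0.37, adjusted p = 7.36e-05, adjusted p = 0.675 with an estimated correlation), as Foxp1 at -0.36. Choroid plexus genes were lower in 23 of 27 (median -0.20, adjusted p = 9.02e-04, adjusted p = 0.785 with an estimated correlation), until IPA 2 or Trp 3 was left out (adjusted p = 0.103 and 0.355). Clock genes were lower in 17 of 18 (median -0.14, adjusted p = 0.00185, adjusted p = 0.486 with an estimated correlation), as Bhlhe40 at -0.38, until Trp 3 was left out (adjusted p = 0.105). Neocortical markers were lower in 16 of 23 (median -0.14, adjusted p = 0.00321, adjusted p = 0.486 with an estimated correlation), as Bcl11b at -0.41, until Trp 1 was left out (adjusted p = 0.0601). Synaptic genes were lower in 28 of 40 (median -0.04, adjusted p = 0.00574, adjusted p = 0.675 with an estimated correlation), as Grm5 at -0.35, with 2 past the threshold over the list alone. Immediate early genes were lower in 23 of 30 (median -0.13, adjusted p = 0.0173, adjusted p = 0.7 with an estimated correlation), as Egr1 at -0.45, until IPA 2 or Trp 1 was left out (adjusted p = 0.45 and 0.19). The lists that did not pass had adjusted p from 0.0735 for the nuclear respiratory chain to 0.924 for antioxidant genes, and 4 of them had a median, mean and test that differed in sign (receptor targets, dentate, heat shock and amyloid genes). Without HFD 3, IPA 3 or Trp 2, 1 gene passed.

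In Trp against IPA, 11 of the 17 list calls ended with the covariates. These were the barrier transport (adjusted p = 0.11), mural (0.504), fatty acid and indole receptor (0.166), astrocyte (0.791), immediate early (0.615), synaptic (0.44), neocortical (0.146), hypothalamic (0.327) and clock lists (0.461), and the choroid plexus (0.646) and striatal (0.978) lists that are covariates themselves. Without HFD 3 and Trp 3 the transport (adjusted p = 0.101), receptor (0.101), choroid plexus (0.249) and clock calls (0.116) ended, and with a replicate block the astrocyte call (0.0839).

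The last comparison asks how far the same genes differed from HFD in both groups. All 64 genes called in Trp against HFD had the same sign in IPA against HFD, 57 of them with an unadjusted p under 0.05, and the median ratio of the IPA to the Trp log2 fold change was 0.638. These genes were picked by their Trp change and both changes share the HFD libraries, so shared signs and smaller IPA changes arise without any change. In simulated groups without change, the 64 genes with the smallest Trp p had the same sign in 60.3 on average (55 to 63 in 20 draws), 24.6 of them (16 to 32) with an unadjusted p under 0.05 in IPA, and a median ratio of 0.508 (0.404 to 0.586). The change was smaller in IPA for 63 of the 64, and for 60.3 (58 to 64) in the simulation. The simulation drew genes independently, so its ranges leave out variation that moves many genes together. Ctss stood at 23.6, 29.1 and 50.6 CPM in HFD, IPA and Trp, and Fos at 28.4, 10.6 and 9.64 CPM. Marcksl1 stood at 95.8 ± 14.4 CPM in HFD, 51.3 ± 1.98 in IPA and 49.8 ± 10.7 in Trp. Mfsd2a stood at 15.5, 23.9 and 32.1 CPM.

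Across genes, the Pearson correlation of both sets of log2 fold changes was 0.699. Both sets share the HFD libraries, which alone gave 0.476 (0.456 to 0.501 in 20 draws) in simulated groups without change, and genes are not independent replicates. The covariance was 0.118, against 0.0447 in the simulation. At an unadjusted p under 0.05, 443 genes were higher in both, where independent lists would share 53.4, and 441 were lower in both, where 56.5 would be shared. Their total of 884 compared with a mean of 143 and a maximum of 168 in the simulated groups. Genes were drawn independently there, so the simulated ranges lack variation that moves many genes together, as tissue makeup can. Other splits of the real libraries gave up to 2966 genes in Trp against HFD and 2040 in IPA against HFD at an unadjusted p under 0.05 in edgeR. How much of the excess arises from such variation was not tested. At adjusted p under 0.05 edgeR gave 0 shared calls, where the simulation gave 0.2 on average. The 3 HFD libraries were not divided between the comparisons, so what both share includes whatever set these HFD libraries apart. By the authors' own calls, 18 genes went the same way in both comparisons (14 up, 4 down) and 0 went opposite ways.

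**Figure D3:**
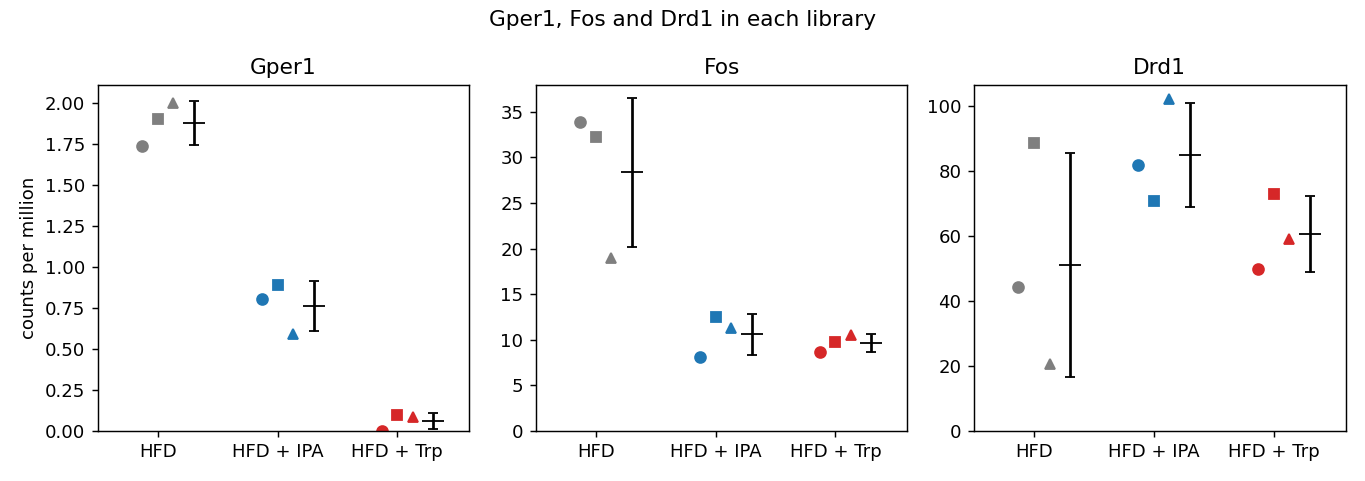
CPM of Gper1, Fos and Drd1 in each of the 9 libraries, with bars for the mean ± SD of each group (n = 3). The means of Gper1 are 1.88 in HFD, 0.76 in IPA and 0.0588 in Trp, the mean of Fos is highest in HFD, and Drd1 ranges from 20.5 to 88.6 within HFD.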

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

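The fit with striatal and choroid plexus means as covariates and the fit without HFD 3 and Trp 3 were chosen after the results were seen, and all other alternatives were planned. HFD 3 and Trp 3 lay apart from the rest of their groups on the second principal component, at -14.4 and 25.7. Leaving them out can raise the counts by that choice alone, so no stronger response is read from that fit. The 64 genes of Trp against HFD became 309 with DESeq2, 97 with no filter on low values, 30 at a mean FPKM of at least 5 (fewer genes tested), 8 in the 6 libraries compared (fewer samples, all 8 among the 64), 23 with a replicate block, 201 with the covariates, 775 without HFD 3 and Trp 3, 28 at a fold of at least 2, and 12 and 119 at adjusted p under 0.01 and 0.1. Leaving out 1 library gave 13 to 323. The 1 gene of IPA against HFD became 168 with DESeq2, 6 with no filter, 0 at a mean FPKM of at least 5, 2 in the 6 libraries compared, 0 with a replicate block, 247 without HFD 3 and Trp 3, and 0 and 2 at adjusted p under 0.01 and 0.1, with 0 to 52 when 1 library was left out. The 0 genes of Trp against IPA became 15 with DESeq2, 3 with no filter, 2 with limma at each pseudocount, 1 with the covariates and 2 without HFD 3 and Trp 3, with 0 to 1 when 1 library was left out. Of the lists called in Trp against HFD, IPA against HFD and Trp against IPA (16, 16 and 17), 0, 0 and 0 remained with an estimated correlation and 2, 0 and 0 were called by fry. The 2 were the microglia and neurogenesis lists (fry adjusted p = 0.0217 each). Trp against IPA had 8 with the covariates and 11 to 21 when 1 library was left out. The ribosomal protein list turned upward in IPA against HFD with the covariates (adjusted p = 1.5e-05, lowest to highest over its alternatives 1.71e-11 to 0.676). The correlation of both responses, 0.699, was 0.841 over genes called in either comparison (0.541 to 0.919 over genes picked in the same way in simulated groups without change), 0.534 with no filter, 0.728 at a mean FPKM of at least 5 and 0.712 to 0.766 without 1 HFD library, and 1 call was shared at adjusted p under 0.1. Where neither fewer genes nor fewer samples account for a change, the cause was not tested. No call of a named gene turned its direction, and in Trp against HFD such calls were lost 64 times over the other settings and 105 times when 1 library was left out. RLE and upper quartile scaling left 67 and 63 genes in Trp against HFD. Replicate numbers did not pair the libraries: same-numbered residuals correlated at -0.196 to 0.048 and others at -0.145 to 0.256, and 1 library was closest to its own number. Depth limits Ffar3, Ffar2, Tnf and Nr1i2, of which 0 to 19 counts per library were found.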

Other observations

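The tests of patterns below, and the genes named, were chosen after the results were seen. Outside the microglia list, 5 further genes that rose in the Trp group were picked by their function once their values were known, so no theme is read from them. Fcgr3, a receptor for IgG, had a log2 fold change of 0.92 (SE 0.10, adjusted p = 0.0049) in Trp against HFD in edgeR, and Mertk, a receptor for the uptake of dying cells, of 0.87 (SE 0.11, adjusted p = 0.00568). Havcr2, the inhibitory receptor TIM-3, stood at 1.36 (SE 0.19, adjusted p = 0.011) and Tlr13, a sensor of bacterial RNA, at 1.36 (SE 0.23, adjusted p = 0.0271). Ncf1, a subunit of the phagocyte oxidase whose exons overlap Gtf2ird2, stood at 0.72 (SE 0.14, adjusted p = 0.0486). In IPA against HFD the same 5 genes had log2 fold changes of 0.27, 0.58, 0.72, 0.54 and 0.43, and none passed.

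Of the other genes that passed in Trp against HFD, 7 are given next, also picked once their values were known. Pnpla2, the adipose triglyceride lipase, rose by 0.90 on the log2 scale (SE 0.10, adjusted p = 0.0051), from 17.2 ± 1.28 CPM to 32.1 ± 2.92 CPM (SD, n = 3), and its relative Pnpla7 rose by 0.79 (adjusted p = 0.0415). Fam107a, an actin-binding protein induced by stress, rose from 396 ± 32.5 CPM to 678 ± 115 CPM (adjusted p = 0.0207). Htra1, a secreted serine protease, rose by 0.74 (SE 0.09, adjusted p = 0.00568). The adhesion genes Nectin1 and Cxadr fell by 0.62 (adjusted p = 0.0451) and 0.63 (adjusted p = 0.0362), the latter with exons that overlap Btg3. Nr1d1, the clock repressor REV-ERB alpha with exons that overlap Thra, fell by 0.61 (adjusted p = 0.0378).

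Over all 18690 genes, 56 had every Trp library above every IPA library and these above every HFD library, and 40 had the opposite order, where chance gives 11.1 per order. The order HFD, Trp, IPA from the highest held for 25, IPA, Trp, HFD for 17, and the 2 orders with HFD in the middle for 7 each. Groups did not overlap, with a mean CPM in 1 of them under 10% of that in the other, in 14 genes of Trp against HFD, 11 of IPA against HFD and 4 of Trp against IPA, of which 6, 1 and 0 passed. Those 6 were Gper1, Apol7a, Gm49395 (32 to 68 counts in HFD, 1 to 4 in Trp, adjusted p = 0.00666, exons that overlap Itga1 and Pelo), the pseudogenes Gm43089 (0 counts in HFD, 12 to 18 in Trp, adjusted p = 0.0216) and Fbxw23 (0 to 3 in HFD, 22 to 47 in Trp, adjusted p = 0.0225), and Gm45861 (0 to 2 in HFD, 14 to 30 in Trp, adjusted p = 0.0271). The 1 was Gm10774, with 28 to 31 counts in HFD and 1 in each IPA library. Its FPKM fell further than its counts, from 2.54 to 2.89 in HFD to 0.014 to 0.018 in IPA. Skida1 had 475 to 550 counts in HFD, 11 to 28 in IPA and 19 to 329 in Trp. It did not pass in IPA against HFD in edgeR (adjusted p = 0.349), while the authors' q was 9.72e-51. The FPKM of Skida1 fell less than its counts, from 2.601 to 2.791 in HFD to 0.567 to 0.997 in IPA. Whether its reads were assigned to another transcript model was not tested. Gm45062, with exons that overlap Glcci1 and Umad1, had 0 counts in HFD, 0 to 1594 in IPA and 594 to 1866 in Trp, and did not pass in Trp against HFD (adjusted p = 0.487). Apol7a, among the 40, stood at 0.29 ± 0.0504 CPM in HFD, 0.113 ± 0.0469 in IPA and 0 in Trp. Tomt, among the 25, stood at 0.458 ± 0.118 in HFD, 0.0236 ± 0.0409 in IPA and 0.17 ± 0.0463 in Trp, with exons that overlap Anapc15.

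Gper1 was near absent in Trp and intermediate in IPA, with 81 to 94 counts in HFD, 25 to 36 in IPA (adjusted p = 0.322 in edgeR) and 0 to 4 in Trp. Trp stood at 3.16% of HFD (95% interval 1.45 to 6.89). The authors' own test, which is not named, called Gper1 lower in both, with q = 0.0243 for IPA and 3.89e-11 for Trp. Its level thus fell in the order of the column codes WTB, HEB and HOB. With the striatal and choroid plexus means as covariates, the log2 fold change of Gper1 in Trp against HFD was -4.89 (SE 0.54), against -4.98 (SE 0.52) without. This argues against makeup by those tissues, while other tissues were not in the fit. Shared reads are argued against by 0 genes with exons over Gper1. None of the 20 tested genes within 500 kb passed over all genes in Trp against HFD. The lowest of them, 6330403L08Rik, stood at -0.45 in Trp and -0.39 in IPA (unadjusted p = 4.03e-04 and 0.00125 in edgeR). The highest, Tmem184a, stood at 2.12 and 1.99 (unadjusted p = 0.0354 and 0.049). Whether the groups differ in the Gper1 gene itself cannot be told apart from a treatment effect, since each group had 1 treatment, and the IPA level of 40.6% of HFD (22.8 to 72.2) may arise either way. The deposited columns of HFD, IPA and Trp carry the codes WTB, HEB and HOB, which the labels do not explain, so whether they belong to this series or to another, such as one of genotypes, stays open, and an effect of the treatments was not tested apart from the groups.

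Microglia genes were higher in Trp than in HFD by a median of 0.61, with an SD of 0.29 between members. Striatal and choroid plexus makeup is argued against by a median of 0.70 with these list means as covariates (camera adjusted p = 2.21e-22, 24 of 25 members higher). Other tissues, such as hypothalamus and thalamus, were not in that fit, so their share stays open. A lower share of neurons would raise other cell types alike. Medians of at most 0.0728 in 5 non-neuronal lists (endothelial, mural, astrocyte, oligodendrocyte and precursor) argue against it for these cells. The ependymal and choroid plexus lists went the other way, with medians of 0.41 and 0.76. The blood cell list had a median of -0.82, with red cell genes as Alas2 at -2.37, Hbb-bs at -1.89 and Hba-a1 at -1.72. This argues against more red cells left in the tissue. Of white cell genes, Ptprc stood at 0.44, Cd4 at 0.53 and Igkc at -0.23, and none passed, so white blood cells stay open. The number of microglia and their transcript levels were not separated, the treatment or any other difference between the groups stays open as untested, and the list call is lost with an estimated correlation (adjusted p = 0.359).

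In 10 genes with at least 5 CPM in the other 8 libraries, the CPM of 1 library fell to under 0.1 of the next lowest library: Dcx, Oprk1, Rasal2 and Creb1 in HFD 3, Phc3 and Fsd1l in Trp 2, Unc5d in Trp 1, Hnrnpa3 and Fgf2 in IPA 3 and Pter in IPA 1. Counts per FPKM shifted with them by a median of -1.53 on the log2 scale, beyond 1 in all 10, where 44 of 119907 pairs of gene and library (0.0367%) fell that far, so that reads assigned to another transcript model may account for these losses. Tissue makeup of those libraries stays open, since the genes were picked for their fall, so the largest fall of a list mean, -1.46, against their smallest, -3.63, decides nothing. Of the 51 genes called in Trp against HFD with a mean FPKM of at least 1, 0 had a shift beyond 0.5, and of all 64 called genes 4 did. These were Gm43089 (-2.67), Gm45861 (1.40), Gm49395 (0.67) and Usp50 (0.56), all except Usp50 among the near absent genes named above. Gm43089 had 0 counts in HFD, where counts per FPKM cannot be measured. No biological explanation was tested.

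With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. By the number of genes with an unadjusted p under 0.05, 2 of 10 splits, the real one included, gave as many in each comparison (real 2112, 1946 and 840, highest other 2966, 2040 and 1351 for Trp against HFD, IPA against HFD and Trp against IPA). For Trp against HFD, 1 of 10 splits gave as many genes as the real 64, with 12 as the highest other, and 5 gave as many lists as the real 16, with 19 as the highest other. For IPA against HFD, 2 gave as many genes as the real 1, with 1 as the highest other, and 4 as many lists as the real 16, with 18 as the highest other. For Trp against IPA, 10 gave as many genes as the real 0, with 1 as the highest other, and 1 as many lists as the real 17, with 13 as the highest other.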
